A study of Mus musculus with 8 samples.

How the data were processed

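The series holds 8 one-colour Affymetrix arrays of total RNA from primary mouse pancreatic ductal epithelial cell cultures, 5 labelled with oncogenic Kras and 1 floxed Pten allele (Kras-Pten, passage 4) and 3 with oncogenic Kras alone (Kras, passage 7). Groups were taken from the genotype given in the labels. The sample titles carry no replicate numbers, so replicates were numbered in accession order and the numbers pair no cultures. The series' design text speaks of cultures set up from 5 and 3 mice, and each array was treated as 1 mouse. Passage differs completely with genotype and could not be a term of any fit.

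Per the labels' protocols, RNA was extracted with Trizol, cleaned on columns and made into biotin-labelled cRNA. Per the submitters' processing notes, MAS5 and Affymetrix Expression Console were used, with versions and settings not given in the sources used here. The deposited values are linear MAS5 signal intensities, one per probe set and array. The 2% trimmed means of the 8 arrays differed by a factor of 1.00106 at most, so the deposited scaling was kept. No detection calls and no control probe sets were used here.

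All 45037 probe sets were read, and a probe set was kept if its signal was at or above the 40th percentile of its array on at least 3 arrays, which left 29412. Signals were analysed as log2(signal + 16). A fold change on this scale understates the change of dim probe sets. Probe sets were named from a table of the platform's annotation, which can be old, updated through gene numbers to the RefSeq gene table of the mouse assembly GRCm38.p6, where 34741 names were matched. Of the probe sets kept, 24593 name 1 gene, 632 several and 4187 none, and no gene was named from a probe set that names several. The table names no probe set for Pten or Kras. The level of Pten had been planned as a check of the labels and was not analysed here. No coordinates are printed, since no genome build is named for the arrays.

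The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), as Kras-Pten minus Kras over all 8 arrays, with Benjamini-Hochberg adjustment over the probe sets kept and a threshold of 0.05 on the adjusted p. All adjusted p-values of genes and probe sets come from this model. Means and SDs are of the linear signals of a group, and SEs are of the log2 fold change. A gene was represented by its kept probe set with the highest mean log2 signal. Before the data were examined, 22 gene lists were fixed, and 21 of them, all but the sex-linked genes, were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera sets a list against all other genes. Each list was tested again with the correlation estimated from the residuals, which was later repeated with each array left out and in the other settings, and with fry, which asks whether its genes move on balance one way, or change in either direction, without comparing them with other genes. The number of members past the threshold is given over all genes tested and adjusted over the list alone. The lists overlap, and Csf3 and Ccl20, for example, belong to both the NF-kB target list and the cytokine list.

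The rule for the genes named was also fixed then. It takes Pten, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose groups do not overlap, or, where fewer than 5 pass in a direction, the 10 with the smallest p in that direction. It adds up to 4 members of each list with the smallest p, 10 genes of the NF-kB and cytokine question (Ccl20, Cxcl1, Il6, Il23a, Ccl2, Csf2, Icam1, Nfkbia, Rela and Ikbke) and the cell identity genes Krt19, Epcam, Cdh1, Vim, Col1a1, Ptprc, Cpa1 and Ins2, whatever their values. The lower genes fell under the second case, since 3 passed. Il6, Ptprc and Cpa1 had no probe set past the filter, and their signals are given without a test.

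The alternatives were quantile normalization, a common 75th percentile, pseudocounts of 1 and 64, no filter, a filter at the 60th percentile, eBayes without a trend or with robust estimation, array weights, the mean over the probe sets of a gene, thresholds of 0.1 or of 0.05 with a fold of 2, each array left out in turn, and the NF-kB list without members of 2 other lists. Further alternatives, a Y-linked covariate and the joint removal of 2 arrays, were added after seeing the data. All 56 splits of the 8 arrays into 5 and 3 were fitted in the same way.

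The code was tested on 5 simulated data sets of 29412 probe sets with the means and spreads of this comparison, each with 200 probe sets changed. It called 40.8% of changes of 1 on the log2 scale and 88.8% of changes of 2, none with the wrong sign, and 4.14% of its calls were of unchanged probe sets. A list shifted by 0.5, the cell cycle genes, was called in all 5 data sets. The simulated noise was independent between probe sets, whereas the estimated correlation of these genes on the real arrays was 0.577. The simulation therefore does not show how camera performs on lists of correlated genes. The number of arrays limits the precision.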

Results

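Gene expression was measured on 8 one-colour Affymetrix arrays in primary mouse pancreatic ductal epithelial cells, the cells that line the ducts of the pancreas, grown in culture from animals 6 weeks old on a mixed FVB and C57B6 background. All cultures carried Pdx1-Cre and a Cre-activated oncogenic Kras allele, so that Cre made in the pancreatic lineage switches the oncogene on. In 3 cultures this was the whole genotype (Kras). In the other 5 cultures 1 floxed Pten allele was present as well (Kras-Pten). Pten encodes the lipid phosphatase that opposes phosphoinositide 3-kinase. The Kras-Pten cultures were at passage 4 and the Kras cultures at passage 7, so passage and genotype cannot be told apart. The comparison asks which transcripts differ when a floxed Pten allele is added to oncogenic Kras, and in particular whether genes controlled by NF-kB do, which the title of the series names. The arrays held 45037 probe sets, of which 29412 passed the filter on dim signals and represented 13800 genes. The 2% trimmed mean signal lay between 99.4 and 99.5 on every array. Over the probe sets kept, the log2 signals of any 2 arrays correlated, across probe sets, at 0.956 to 0.970 among the Kras-Pten cultures, at 0.920 to 0.943 among the Kras cultures and at 0.932 to 0.957 between the genotypes, so the Kras cultures resembled each other less than the Kras-Pten cultures did. Each Kras array even correlated better on average with the Kras-Pten arrays (0.940, 0.941 and 0.948 for replicates 1, 2 and 3) than with the other Kras arrays (0.932, 0.937 and 0.926). The table of probe set names used here names no probe set for Pten or Kras. The targeted gene was therefore not analysed here, and the genotype labels were not checked against it.

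Between the genotypes, 8 named genes were higher and 3 were lower in Kras-Pten cultures at an adjusted p under 0.05 in limma. Dram1, a regulator of autophagy induced by p53, rose from a signal of 113 ± 37.8 (SD, n = 3) to 868 ± 412 (SD, n = 5), a log2 fold change of 2.68 ± 0.38 (SE, adjusted p = 0.037). Lrg1, a secreted acute-phase glycoprotein, rose from 13.6 ± 12.1 to 172 ± 71.6, also by 2.68 (SE 0.32, adjusted p = 0.017), and only 1 of the 3 Kras arrays was at or above its 40th percentile for it. Csf3, the granulocyte colony-stimulating factor and a known NF-kB target, rose from 1255 ± 152 to 2699 ± 307, a log2 fold change of 1.10 ± 0.13 (SE, adjusted p = 0.017). Gpd2, the mitochondrial glycerol-3-phosphate dehydrogenase, rose by 1.18 ± 0.17 (SE, adjusted p = 0.038), and Igf2r, the receptor that carries IGF2 and mannose 6-phosphate proteins to lysosomes, by 1.03 ± 0.15 (SE, adjusted p = 0.041). The other 3 genes that rose were the membrane transporter family members Slc35g1 (log2 fold change 1.35) and Slc35a5 (1.20), and Zfp809, a zinc finger protein known to silence retroviral sequences (1.16). A second Igf2r probe set rose by 1.23 (adjusted p = 0.0094), while 1 of the 3 other kept probe sets of Slc35a5 moved in the opposite direction.

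Glrx, a glutaredoxin that reduces protein thiols, fell from 705 ± 31.9 (SD, n = 3) to 399 ± 28.4 (SD, n = 5), a log2 fold change of -0.80 ± 0.11 (SE, adjusted p = 0.035 in limma). Cadm1, a cell adhesion molecule, fell from 810 ± 127 to 397 ± 44.0, with a log2 fold change of -0.99 ± 0.14 (SE, adjusted p = 0.037), and its 3 other kept probe sets were lower too. Col7a1, the collagen of the anchoring fibrils under epithelia, fell from 221 ± 30.9 to 76.1 ± 19.7, with a log2 fold change of -1.38 ± 0.19 (SE, adjusted p = 0.037). The next genes by p did not pass the test. They included the receptor tyrosine kinase Axl, with a log2 fold change of -1.23 ± 0.22 (SE, adjusted p = 0.105), whose second probe set stood at -0.17, the small GTPase Rhou at -1.16 (adjusted p = 0.205), and Nnt, the mitochondrial nicotinamide nucleotide transhydrogenase, at -0.77 (adjusted p = 0.211). Itgb7, Wnt10a, Pfkfb4 and Tmem106b completed the 10 with the smallest p among lower genes, with log2 fold changes between -1.05 and -0.76 and adjusted p between 0.107 and 0.174. For each of the 11 genes that passed, every Kras-Pten array lay on the same side of every Kras array.

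**Figure D1:**
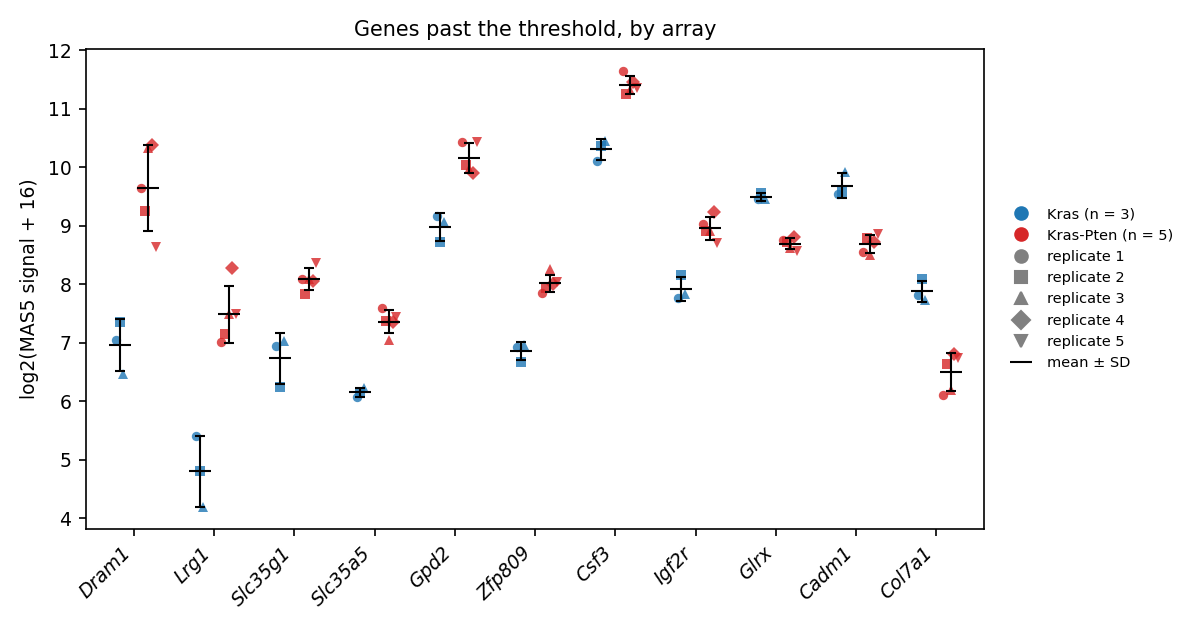
The y axis gives log2 of the MAS5 signal plus 16 on each array for the 11 genes that passed the test, Kras cultures (n = 3) in blue and Kras-Pten cultures (n = 5) in red, with the mean and SD as bars. The groups do not overlap for any of the 11 genes, with the largest gaps for Dram1 and Lrg1, at log2 fold changes of 2.68 each.

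In all, 15 probe sets were higher and 7 lower at an adjusted p under 0.05 in limma, and 4 of these 22 have no gene named. At an unadjusted p under 0.05 there were 1306 higher and 1017 lower probe sets, and the groups did not overlap for 5.37% of the probe sets, against the 3.57% that chance gives for 5 arrays against 3. The count depended on single arrays. Without Kras replicate 3 it was 211 higher and 33 lower, which included all 22, and without Kras replicate 2 it was 6 higher and 0 lower, with 813 lower at an unadjusted p under 0.05. Leaving out any 1 of the Kras-Pten cultures gave between 4 and 9 higher and between 0 and 2 lower, and without Kras replicate 1 there were 23 higher and 9 lower.

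Among NF-kB target genes, 48 of the 54 listed were measured, 29 higher and 19 lower in Kras-Pten cultures, with a median log2 fold change of 0.19. As a group they were shifted upwards against all other genes (adjusted p = 0.044, camera in limma with a preset correlation), but adjusted p = 0.879 with an estimated correlation. Csf3 was the 1 member that passed over all genes tested, and adjusted over the list alone there were 3, namely Csf3, Saa3 and Ccl20. Saa3, an acute-phase serum amyloid, had a signal of 944 ± 473 (SD, n = 5) in Kras-Pten against 157 ± 87.6 (SD, n = 3) in Kras cultures, a log2 fold change of 2.52 ± 0.41 (SE, adjusted p = 0.069 in limma over all genes). Ccl20, a chemokine that attracts CCR6-bearing lymphocytes and dendritic cells, had 712 ± 353 against 156 ± 210, a log2 fold change of 2.82 ± 0.71 (SE, adjusted p = 0.299), and Kras replicate 3, at 397, was above the lowest Kras-Pten array, at 376. Ccl5, a T-cell chemokine, went the other way, at -1.92 ± 0.58 (SE, adjusted p = 0.410). The intercellular adhesion molecule Icam1 stood at 0.73, the neutrophil chemokine Cxcl1 at 0.26, the monocyte chemokine Ccl2 at 0.27, Il23a at 0.39 and Csf2 at 0.060, with adjusted p between 0.714 and 0.990. Il6 was too dim for the test, at a signal of 11.6 ± 6.71 (SD, n = 5) against 4.90 ± 3.19 (SD, n = 3). Leaving out Kras replicate 1 lowered the median of the list to 0.025 (adjusted p = 0.496), leaving out Kras-Pten replicate 4 to 0.090 (adjusted p = 0.160) and leaving out Kras-Pten replicate 5 to 0.14 (adjusted p = 0.087). The call was also lost with array weights (0.11, adjusted p = 0.161) and with the mean over the probe sets of each gene (0.11, adjusted p = 0.106).

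Of the broader list of cytokines and chemokines, 36 of 44 were measured, 25 higher and 11 lower, with a median of 0.13 (adjusted p = 0.181, camera). This list passed without Kras replicate 2 (0.20, adjusted p = 0.012) at the preset correlation but not with it estimated, and without Kras replicate 1 its median was 0.030 (adjusted p = 0.605). Csf3 passed over all genes, and Csf3, Ccl20 and Cxcl3 passed adjusted over the list alone. Cxcl3, a neutrophil chemokine, stood at 1.20 ± 0.33 (SE, adjusted p = 0.350 in limma over all genes). The signalling components upstream of NF-kB did not shift as a group, with 18 of the 32 measured higher, a median of 0.013 (adjusted p = 0.787, camera) and no member past the test over all genes or adjusted over the list alone. The transcription factor subunit Rela stood at 0.040 ± 0.16 (SE), the inhibitor Nfkbia at -0.33 ± 0.23, the kinase Ikbkb at -0.28 ± 0.12 and Ikbke at -0.087 ± 0.26. All 5 kept probe sets of Nfkbia were lower in Kras-Pten cultures and none passed the test, while the 2 probe sets of Nfkb2 pointed in opposite directions, at 0.43 and -0.49.

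**Figure D2:**
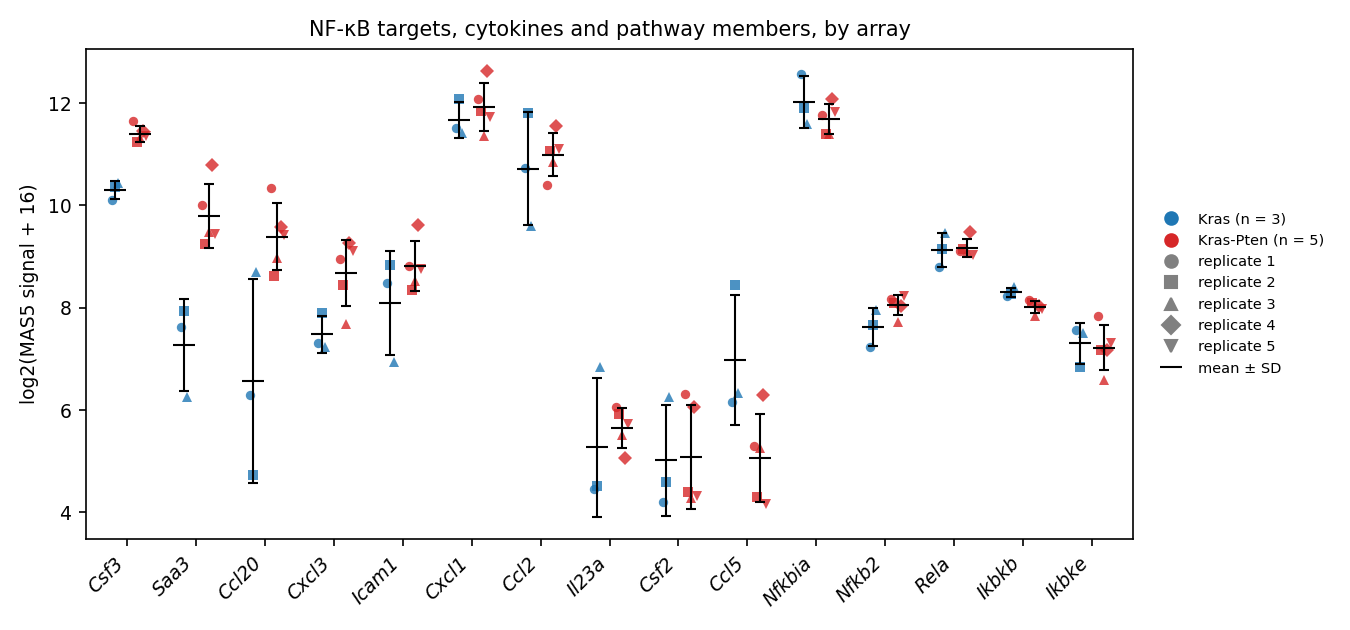
The y axis gives log2 of the MAS5 signal plus 16 on each array for NF-kB targets, cytokines and pathway members, Kras cultures (n = 3) in blue and Kras-Pten cultures (n = 5) in red, with the mean and SD as bars. Csf3, Saa3 and Ikbkb show no overlap between the genotypes, whereas the groups overlap for Ccl20, Cxcl1, Ccl2, Il23a, Csf2, Rela, Nfkb2 and Ikbke.

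Components of the PI3K, AKT and PTEN pathway moved both ways, with 16 of the 29 measured higher and a median of 0.038 (adjusted p = 0.953, camera). No member passed over all genes, and Irs2, the insulin receptor substrate, passed adjusted over the list alone, with a log2 fold change of 1.11 ± 0.24 (SE, adjusted p = 0.211 in limma over all genes). Irs2 was dim in Kras cultures, with a mean signal of 12.9, and had no second kept probe set. Only 1 of the 3 Kras arrays was at or above its 40th percentile for it. FOXO target genes, which AKT restrains through the FOXO factors, were lower for 17 of the 23 measured, with a median of -0.13 (adjusted p = 0.189, camera). They passed without Kras replicate 1 (-0.21, adjusted p = 0.014) at the preset correlation but not with it estimated. Irs2 is on this list as well. It passed adjusted over the list alone together with the cyclin Ccng2, which stood at -0.66 ± 0.16 (SE, adjusted p = 0.254). RAS-MAPK output genes were higher for 13 of the 23 measured, with a median of 0.16 (adjusted p = 0.482, camera) and no member past the test in either way. Ccnd1, the D-type cyclin, stood at -0.38 and the feedback inhibitor Spry4 at 0.54.

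Ductal epithelial markers formed the group with the largest shift. Of 25 listed, 21 were measured and 18 were higher in Kras-Pten cultures, with a median of 0.48 and a mean of 0.90 (adjusted p = 8.57e-05, camera), but adjusted p = 0.879 with an estimated correlation. No member passed over all genes, and the chloride channel Cftr and the apical membrane protein Prom1 passed adjusted over the list alone. Cftr had a signal of 58.5 ± 18.3 (SD, n = 5) against 7.49 ± 4.91 (SD, n = 3), a log2 fold change of 1.65 ± 0.25 (SE, adjusted p = 0.052 in limma over all genes). Prom1 had 2713 ± 1319 against 384 ± 441, a log2 fold change of 3.27 ± 0.64 (SE, adjusted p = 0.158). The epithelial adhesion molecule Epcam had signals of 134, 158 and 4478 in the 3 Kras cultures and of 1739 to 3668 in the Kras-Pten cultures, so Kras replicate 3 lay above every Kras-Pten array. Krt19, the ductal keratin, and Cdh1, E-cadherin, stood at 0.65 ± 0.58 (SE) and 0.73 ± 0.41 (SE). Leaving out Kras replicate 2 lowered the median of the list to 0.21 (adjusted p = 0.063, camera), leaving out Kras replicate 3 raised it to 0.91, and leaving out Kras-Pten replicate 4 raised it to 0.88.

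Genes of the epithelial to mesenchymal transition were lower for 15 of the 21 measured, with a median of -0.13 (adjusted p = 0.113, camera). The list passed without Kras replicate 1 (-0.55, adjusted p = 0.022) or replicate 3 (-0.45, adjusted p = 0.029), with array weights (-0.49, adjusted p = 0.017) and without the filter on dim probe sets (-0.21, adjusted p = 0.023). All these calls were at the preset correlation, and none held with it estimated. Without Kras replicate 2 the median of the list was -0.049 (adjusted p = 0.629). The adhesion receptor Cd44 at 0.75 ± 0.16 (SE, adjusted p = 0.205 in limma over all genes) and N-cadherin, Cdh2, at -1.20 ± 0.26 (SE, adjusted p = 0.211) passed adjusted over the list alone, and none passed over all genes. Tgfb2 stood at -1.06 and the transcription factor Snai2 at -0.81. The intermediate filament gene Vim did not separate the genotypes, with a log2 fold change of -0.035 ± 0.66 (SE). Its signal was 8034 and 7911 in Kras replicates 1 and 2, where Epcam was low, and 870 in Kras replicate 3. Of the matrix proteases and their inhibitors, 11 of the 22 measured were higher and 11 lower (median 0.0057, adjusted p = 0.787, camera). The matrix-degrading enzymes Mmp7 at 1.49, Adamts1 at 1.10, Adam8 at 1.14 and Mmp11 at -0.72 passed adjusted over the list alone, but none did over all genes (adjusted p from 0.254 to 0.401 in limma).

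**Figure D3:**
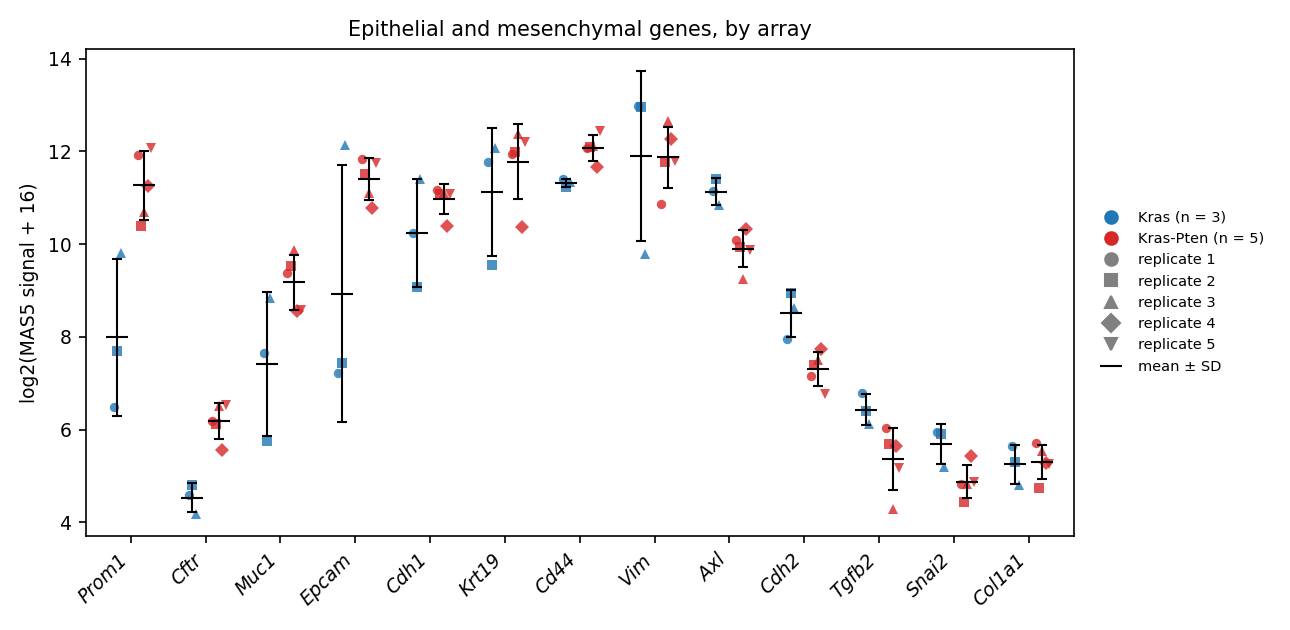
The y axis gives log2 of the MAS5 signal plus 16 on each array for epithelial and mesenchymal genes, Kras cultures (n = 3) in blue and Kras-Pten cultures (n = 5) in red, with the mean and SD as bars. Kras replicate 3 (blue triangle) has the highest Epcam signal, 4478, and the lowest Vim signal, 870, while Kras-Pten replicate 4 (red diamond) has the lowest Krt19 and Cdh1 signals of its group.

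Markers of other pancreatic and stromal cell types did not shift as groups at an adjusted p under 0.05 in camera. Acinar markers were higher for 7 of the 10 measured, with a median of 0.097 (adjusted p = 0.113). The acinar transcription factor Nr5a2 at 1.02 ± 0.24 (SE) and the colipase gene Clps at 0.70 ± 0.21 (SE) passed adjusted over the list alone. Both were dim, with Kras means of 10.7 and 8.27, and the carboxypeptidase gene Cpa1 was too dim for the test. Endocrine markers had a median of 0.070 over the 8 measured (adjusted p = 0.482), and Ins2 had a signal of 24.3 ± 9.05 (SD, n = 5) against 23.7 ± 11.6 (SD, n = 3). Fibroblast and stellate markers had a median of -0.044 over 18 genes (adjusted p = 0.368). Of these, Fbln2, an extracellular matrix glycoprotein, passed adjusted over the list alone at -0.68 ± 0.16 (SE), and Col1a1 was at 24.7 against 23.2. Leukocyte markers had a median of 0.14 over 9 genes (adjusted p = 0.368), and Ptprc, the pan-leukocyte CD45 gene, was too dim for the test. Endothelial markers had a median of -0.031 over 10 genes (adjusted p = 0.855). Gastric and intestinal metaplasia markers had a median of 0.11 over 17 genes (adjusted p = 0.419), and the intestinal transcription factor Cdx2 stood at 0.69 ± 0.22 (SE, adjusted p = 0.437 in limma). No member of the endocrine, leukocyte, endothelial or metaplasia lists passed adjusted over the list alone.

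Interferon-stimulated genes were lower for 20 of the 23 measured, with a median of -0.17 (adjusted p = 0.044, camera), but adjusted p = 0.879 with an estimated correlation. No member passed over all genes or adjusted over the list alone. The antiviral gene Ifit1 stood at -1.32 ± 0.50 (SE, adjusted p = 0.544 in limma), Rsad2 at -0.81, the transcription factor Irf7 at -0.66 and Stat2 at -0.55. Kras replicate 2 had the highest mean of the list, and without it the median was 0.016 (adjusted p = 0.962), so the direction turned. The call was also lost without Kras replicate 3 (-0.21, adjusted p = 0.243) and without Kras-Pten replicate 2 (-0.22, adjusted p = 0.065), replicate 3 (-0.081, adjusted p = 0.216) or replicate 5 (-0.12, adjusted p = 0.215).

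The remaining lists did not pass in camera. Cell cycle genes were higher for 24 of the 34 measured, with a median of 0.049 (adjusted p = 0.482), and the replication licensing gene Mcm2 stood at 0.64 ± 0.24 (SE, adjusted p = 0.534 in limma), although its second probe set was at -0.29. This list passed upwards without Kras replicate 1 (0.27, adjusted p = 7.61e-05) and downwards without Kras replicate 3 (-0.14, adjusted p = 0.048), both with the preset correlation, against an estimated one of 0.577 over all 8 arrays (adjusted p = 0.948). Genes of the p53 response and senescence had a median of 0.060 over 22 genes (adjusted p = 0.907), and the cell cycle inhibitor gene Cdkn2a stood at -0.74 ± 0.21 (SE, adjusted p = 0.379). The p53 list passed upwards without Kras replicate 3 (0.33, adjusted p = 0.0045), also with Kras-Pten replicate 4 left out as well (0.35, adjusted p = 0.015). Both calls were at the preset correlation and were lost with it estimated. Without Kras replicate 1 the median of the p53 list was -0.17 and it did not pass. Glycolysis genes had a median of -0.067 over 15 genes (adjusted p = 0.787). Pdk1, the kinase that keeps pyruvate out of mitochondrial oxidation, passed adjusted over that list alone at 1.32 ± 0.20 (SE, adjusted p = 0.055 in limma over all genes), with 1 of its 2 other probe sets at -0.24. Sterol and fatty acid synthesis genes had a median of -0.0026 over 24 genes (adjusted p = 0.533), and stress-responsive genes a median of 0.00035 over 18 genes (adjusted p = 0.788), with the asparagine synthetase gene Asns at -0.58 ± 0.18 (SE, adjusted p = 0.410). The stress list passed downwards without Kras replicate 1 (-0.18, adjusted p = 0.034) at the preset correlation but not with it estimated. Apart from Pdk1, no member of these 5 lists passed adjusted over its list alone. The median was positive and the test pointed down for the p53 and stress lists, the median and the mean of the glycolysis and sterol lists differed in sign, and the sterol test pointed up.

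**Figure D4:**
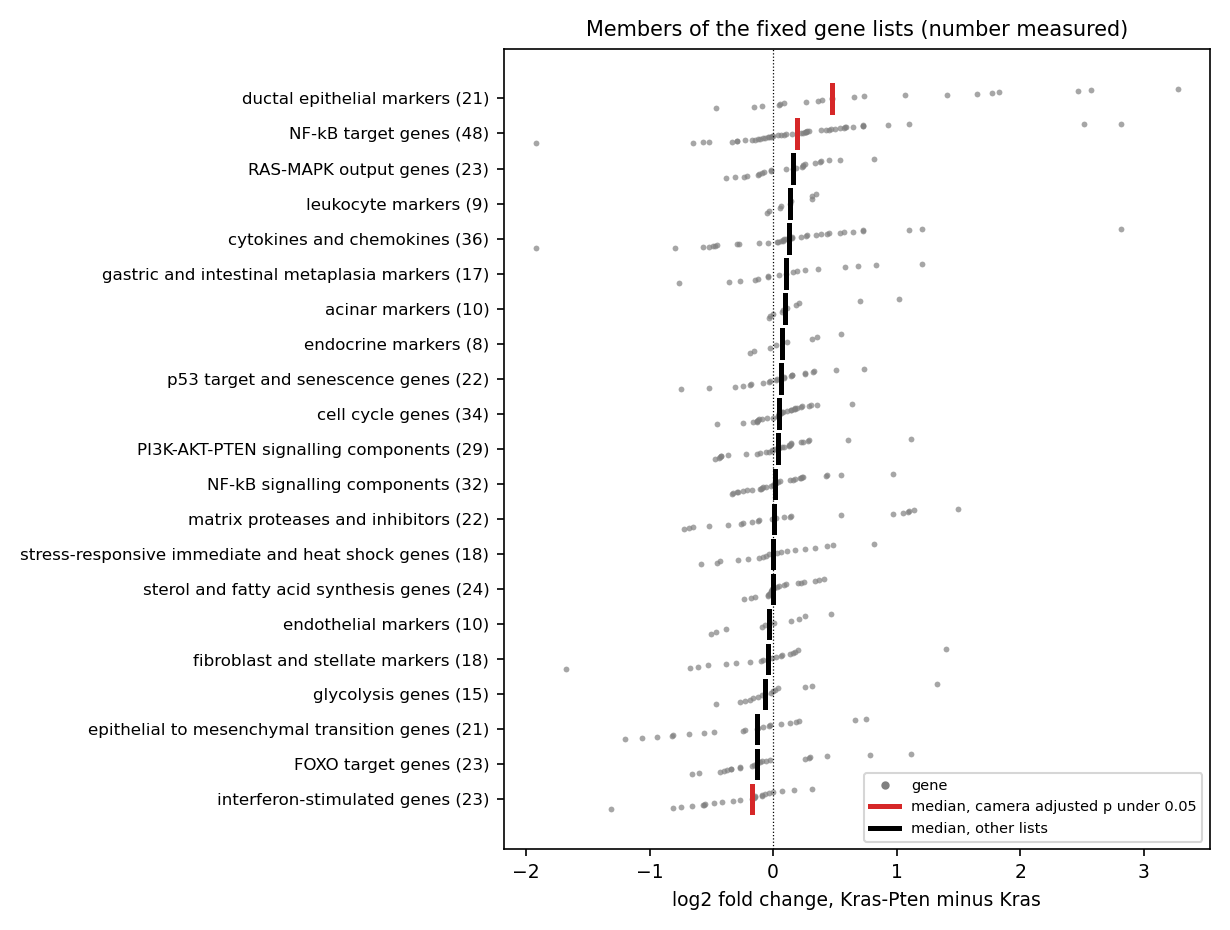
Each grey point is the log2 fold change of 1 gene, Kras-Pten minus Kras, on the x axis, by gene list on the y axis with the number of genes measured, and each vertical bar is the median of its list. The 3 lists that passed in camera, with red bars, have medians of 0.48 for ductal epithelial markers, 0.19 for NF-kB targets and -0.17 for interferon-stimulated genes.

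Taking the 21 lists by other tests, none passed with the correlation estimated per list, where 0 also had an unadjusted p under 0.05. With 1 array left out, 23 list calls were made at the preset correlation and 0 with the correlation estimated (lowest adjusted p = 0.313). By fry, 0 lists passed in one direction, 1 had an unadjusted p under 0.05, and 8 passed for changes in either direction, namely the FOXO targets (adjusted p = 0.0023), PI3K, AKT and PTEN components (0.0055), cytokines and chemokines (0.0055), glycolysis genes (0.0057), acinar markers (0.0086), matrix proteases (0.011), mesenchymal transition genes (0.041) and NF-kB targets (0.043), but not the ductal markers (0.063) or interferon-stimulated genes (0.642). The fry test in either direction sets no list against other genes. Of all 29412 probe sets kept, 2323 had an unadjusted p under 0.05 in limma. This fry test was not run over the splits or with an array left out, so the 8 passes do not set these lists apart from other genes. The cultures came from animals of both sexes by their sex-linked transcripts. Xist, the RNA of the inactive X chromosome, was at 1485 to 2660 in Kras-Pten replicates 1, 2 and 5 and Kras replicate 1, and at 39.8 to 51.9 in the other 4 cultures.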

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

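The tests of fibroblasts, of sequence differences and with the Y-linked covariate were chosen only after the results were seen, the comparison within each sex was added after seeing the data, with its prediction written before its own result, and the estimated correlation, itself planned, was read as a test of correlated members only then. In a comparison of each named gene and list within the 5 Kras-Pten cultures, 5 of 136 values stood far from the rest. Chance gives about 1 in 20, so this number is not beyond chance. The values are not independent either, since Krt19 and Cdh1 belong to the ductal list, whose mean is among them. All 5 were in replicate 4. Its log2 signal was the highest of its group for Nr5a2 (6.47, next 5.62) and for Rela (9.47, next 9.15), and the lowest for Krt19 (10.4, next 11.9) and Cdh1 (10.4, next 11.1). Its mean over the ductal epithelial markers, relative to the mean of all 8 arrays, was the lowest too (-0.23, next 0.34).

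The first pattern is the set of 22 probe sets that differed between the genotypes. Of the 56 splits of the 8 arrays into 5 and 3, the real one included, 2 gave as many higher probe sets as the real split (15, highest other 65) and 2 as many lower (7, highest other 7), which is under 5%. The real split did not call the most, however. The split of Kras-Pten replicate 4 and Kras replicates 1 and 2 from the rest called 72 in all and points to a structure of the samples other than genotype. Chance is therefore not excluded. The 6 probe sets that did not pass with the Y-linked covariate had a median absolute log2 fold change of 1.24 (median SE 0.16) without and 1.22 (median SE 0.18) with it. A larger SE ended their call and hardly a smaller fold. They were called on the same arrays, which favours folds that hold, so this adds no evidence on sex. Both genotypes had cultures of high and of low Xist, and the genotypes did not overlap for any of the 22 probe sets. A difference set by sex alone would be expected to overlap, which argues against unequal sexes as the whole cause. The median ratio of the difference within a sex to the overall one was 0.886 at high Xist (3 Kras-Pten, 1 Kras) and 1.09 at low Xist (2 and 2). This ratio adds no evidence, since it was taken over probe sets called on the same arrays, which favours values near 1. Its high Xist side also rests on 1 Kras culture. Of the 8 genes with further probe sets, 7 had one in the same direction at an unadjusted p under 0.05. This argues against a sequence difference under a single probe set as their whole cause, Slc35a5 apart. Whether probe sets of a gene share target sequence was not checked. For Slc35a5, 1 of 3 other probe sets rose at that limit (0.49, unadjusted p = 0.046 in limma), and another stood at -0.30. A sequence difference stays open for Slc35a5 (median of the others 0.30 against 1.20) and Klhl32, and for part of the change of Vamp3 (0.59 against 1.94). It also stays open for the 10 probe sets with no second one, such as those of Lrg1, Csf3, Dram1 and Col7a1. Genotype and passage cannot be told apart, since the genotypes share 0 passages, and the parental strain mix of each mouse stays open, as untested.

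The second pattern is the higher level of ductal epithelial markers in Kras-Pten cultures. A median as far from 0 as the real 0.48 came from 19 of the 56 splits, so chance cannot be excluded, and the highest other median, 1.05, came again from setting Kras-Pten replicate 4 and Kras replicates 1 and 2 against the rest. The tables argue against fibroblasts in the Kras cultures, which would bring abundant collagen transcripts, since the mean log2 signal of Col1a1, Col1a2 and Col3a1 was -0.13 in Kras relative to Kras-Pten cultures (SE 0.23), and -0.064 and 0.12 in Kras replicates 1 and 2, where Epcam was low and no such signal exceeded 58.6. Other fibroblast markers were mixed, with 8 of the list higher and 10 lower in Kras-Pten cultures. Col6a1 was at 102 and 211 in these 2 cultures against a Kras-Pten mean of 22.6, and Bgn at 12.2 and 56.3 against 111. The mean of the fibroblast list was the highest in Kras replicate 2 (0.61, next 0.20) and stood at -0.14 in Kras replicate 1. Genotype, passage and differences between single cultures in epithelial state stay open.

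The third pattern is the upward shift of the NF-kB targets. A median as far from 0 as 0.19 came from 10 of the 56 splits (highest other 0.29), so chance cannot be excluded for the list as a whole. Members that rise and fall together within a genotype are a candidate explanation of the call, since the unadjusted camera p was 0.256 once the correlation was estimated. Csf3 passed on its own, but lost its call in 6 of 20 alternatives, among them without Kras replicate 2 (1.13, adjusted p = 0.066), and genotype, passage and a sequence difference stay open for it. Of the other counts, 45 of the 56 splits called at least as many lists as the real 3 (highest other 11), and 34 gave an interferon-stimulated median as far from 0 as 0.17 (highest other 0.75), so chance cannot be excluded for either.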

How the results depend on the processing

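The Y-linked covariate, the joint removal of 2 arrays and the estimated correlation in the other settings were chosen after seeing the data, and the covariate was run although its range over the arrays, 1.65 on the log2 scale, was below the 2 that the plan required. No paired analysis was possible because the labels give no shared replicate numbers. The alternatives meant for the Pten level were not run, since no probe set is named for it. Against 15 higher and 7 lower probe sets, there were 11 to 18 higher and 5 to 8 lower under both scalings, both pseudocounts, both filters, robust estimation, array weights and the further limit of a fold of 2. Without a trend there were 10 higher and 0 lower (975 lower at an unadjusted p under 0.05). Over the means per gene there were 5 higher and 3 lower, with the Y-linked covariate 3 lower, and at an adjusted p under 0.1 there were 42 and 13. Leaving out 1 array gave 4 to 211 higher and 0 to 33 lower, the most without Kras replicate 3, and leaving out Kras replicate 3 and Kras-Pten replicate 4 together gave 281 and 47. Both of these settings kept all 22 probe sets. The 11 named genes that passed kept their direction in all 220 fits over 20 alternatives and their call in 126. Since their groups do not overlap, leaving out arrays, array weights, other pseudocounts, filters or eBayes settings could not turn the direction. For those settings the kept direction is therefore no evidence of robustness. Of the 11, 0 passed without Kras replicate 2, 6 without Kras replicate 1, 11 without Kras replicate 3, and 1 or 2 when any 1 Kras-Pten culture was left out. The NF-kB median fell to 0.11 with array weights (adjusted p = 0.161) and over gene means (0.11, adjusted p = 0.106), to 0.056 without both arrays (adjusted p = 0.173), and ranged from 0.025 to 0.24 with 1 array left out. It stayed at 0.19 with an estimated correlation (adjusted p = 0.879) and in fry (adjusted p = 0.747), where only the test changes, and over all alternatives its adjusted p ran from 0.0015 to 0.879. The number of lists that passed was 1 to 6 with 1 array left out and 0 with an estimated correlation or in one direction by fry. With the correlation estimated in each of the 20 settings, 1 list call remained, the ductal markers without both arrays (1.03, adjusted p = 0.024). These 2 arrays stand apart from their groups on the ductal list itself. Its mean relative to all 8 arrays was 0.53 in Kras replicate 3, against -1.05 and -1.17 in replicates 1 and 2. In Kras-Pten replicate 4 it was -0.23, the lowest of that group. Leaving out these 2 arrays therefore widens the shift by construction, and the call is no independent support. The medians of 3 lists changed sign between the fit to all arrays and one with 1 array left out, where at least 1 of those 2 fits passed. They ranged from -0.55 to 0.016 for interferon-stimulated genes, from -0.14 to 0.27 for cell cycle genes and from -0.18 to 0.19 for stress-responsive genes. The p53 median ranged from -0.17 to 0.33 and passed only without Kras replicate 3 and without both arrays. Interferon-stimulated genes also lost their call with a common 75th percentile (-0.18, adjusted p = 0.058), a pseudocount of 1 (-0.25, adjusted p = 0.067), the filter at the 60th percentile (-0.17, adjusted p = 0.096), the Y-linked covariate (-0.10, adjusted p = 0.327) and without both arrays (-0.41, adjusted p = 0.053). Over all alternatives, values that passed in neither fit also changed sign, in 38 cases over 15 genes and in 49 over 13 lists, and these were not counted as reversals. Fewer arrays and fewer genes tested account for part of these differences by construction, and otherwise the cause was not tested. Dim probe sets limit what can be seen, since 15625 were below the filter.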

Other observations

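The genes of this paragraph fall outside the rule for named genes and were chosen after their values were seen, and both list tests of the last paragraph were chosen only after the results were seen. Through a probe set other than the brightest of the gene, 3 further genes passed in limma, all higher in Kras-Pten cultures. They were the vesicle fusion protein gene Vamp3 (log2 fold change 1.94, adjusted p = 0.0037), the glutamate transporter gene Slc1a1 (1.82, adjusted p = 0.017) and Klhl32 (1.42, adjusted p = 0.026), whose brightest probe set stood at 0.03. Among genes just outside the threshold, the carbonic anhydrase gene Car9 stood at 1.61 ± 0.24 (SE, adjusted p = 0.052), the lysosomal protease gene Ctsh at 1.71 (adjusted p = 0.154), the GABA receptor subunit gene Gabrp at 1.50 (adjusted p = 0.158) and the secretory pathway transcription factor gene Xbp1 at 1.27 (adjusted p = 0.108). The iron and copper plasma protein gene Cp was already abundant in Kras cultures and stood at 0.98 (adjusted p = 0.205). Lcn2, an NF-kB target, was among the brightest transcripts in every culture, at signals of 8384 to 12647, and was the brightest of all on Kras-Pten replicate 4, so a small difference between the genotypes cannot be judged from it.

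The largest differences on the arrays belonged to probe sets with no gene named. The signal of 1452426_x_at was 3732 ± 1812 (SD, n = 5) in Kras-Pten and 39.4 ± 35.1 (SD, n = 3) in Kras cultures, and that of 1431214_at was 3937 ± 1662 against 84.7 ± 22.8. In both, Kras-Pten replicate 2 had the lowest signal of its group, 618 and 1102. In the other direction, 1418357_at had 34.0 ± 25.7 against 301 ± 69.8.

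The 3 Kras cultures differed in more than epithelial markers. Relative to the mean of all 8 arrays, the mean over the ductal epithelial list was -1.05, -1.17 and 0.53 in Kras replicates 1, 2 and 3, that over p53 and senescence genes was -0.51, -0.27 and 0.72, and that over cell cycle genes was 0.35, -0.04 and -0.42.

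Since Car9 and Pdk1 are known targets of hypoxia, a hypothesis was that genes induced by low oxygen may be higher in Kras-Pten cultures. The test is on a list of other such genes, of which 7 are on lists tested before, Slc2a1 and Pfkfb3 among them. Pfkfb4, which had also been seen and was lower (-0.85, adjusted p = 0.165 in limma), was left out of the list like Car9 and Pdk1. Of 23 measured, 10 were higher and 13 lower, with a median of -0.034, and 36 of the 56 splits gave a median as far from 0, so the list did not shift beyond chance. Single members ran from -0.82 (Bnip3) to 0.49 (Higd1a). The 16 on no earlier list had a median of -0.11, with 13 of the 56 splits as far from 0. A second hypothesis was that acute-phase genes may be higher as a class, beyond Lrg1, Saa3, Hpx and Cp. Of 21 other members, of which 5 had been named or listed before, Cd14 and Lcn2 among them, 17 were higher and 4 lower, with a median of 0.31, the largest for Hp at 2.45 ± 0.87 (SE) and Orm1 at 2.12 ± 0.75 (SE), and none passed in limma, where 3 were higher at an unadjusted p under 0.05. Hp was at 1034 in Kras-Pten replicate 4, at 36.8 to 218 in the other Kras-Pten cultures and at 50.2 in Kras replicate 3. Orm1 was at 391 in Kras replicate 1, within the Kras-Pten range of 158 to 513. For the list, a median as far from 0 came from 5 of the 56 splits (highest other 0.37), so the shift was not separated from chance, and a smaller one is not excluded. The 16 not named before had a median of 0.30, with 6 of the splits as far from 0.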
